A study of Mus musculus with 6 samples.

How the data were processed

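ATAC-seq, which cuts open chromatin with a transposase, was run on basal stem cells sorted from mouse prostates. There were 6 libraries, 3 from naive prostates and 3 from inflamed prostates. Per the labels' protocols, inflammation was set off in a mouse strain whose prostate expresses ovalbumin by transfer of activated ovalbumin-specific T cells from OT-1 mice, and prostates were taken after 7 days. The cells were gated as CD45-negative, CD31-negative, Sca-1-positive and CD49f-positive, a gate that should leave out leukocytes and endothelial cells. The labels give the genotype as WT for the naive libraries and as POET3 for the inflamed ones, while the extraction protocol speaks of POET3 mice in both groups. The labelled genotype therefore coincides with the group.

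Only a merged list of genomic regions was used here. It has 3 columns, chromosome, start and end, and its values are coordinates, with no signal, fold change, p-value, direction or value per library. Per the submitters' processing notes, the tools were BWA 0.7.17-r1188, SAMtools, HOMER 4.8 and edgeR, on genome build mm10. No source used here explains their order, thresholds or filters, or whether regions were called per library or on pooled libraries. The name under which the authors deposited the list strings together abbreviations, among them "sorted", "rmdup", "edge", "diff" and "merged". They may stand for an order of steps with removal of duplicates and merging of region sets. A number beside "edge" may be a cut-off, but what it limits and what was merged are not stated. The name contains "diff" and the submitters' processing notes name a tool for differential tests. It was therefore read as a list of differing regions. Neither source says which group had the higher signal at a region. The depth per library is unknown, no replicate error can be given, and no test between naive and inflamed libraries could be fitted. A filter on fold or significance before deposit fixes what can appear in the list, and regions just short of it are lost without trace.

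Starts were counted from 0 in the list and are printed from 1. Genes came from a RefSeq table of assembly GRCm38.p6, whose primary chromosomes are those of mm10. Of its 49997 genes, 49943 lay on chromosomes 1 to 19, X and Y, and 21887 of these were protein-coding. The table gives each gene's span without strand or exons, and no genome sequence was used here. Transcription start sites were therefore replaced by gene ends (either end of the span), exons and introns were not told apart, GC content was not matched, and the 26 consensus motifs fixed beforehand were not searched.

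Each region was placed by its centre. A region inside a protein-coding gene was given to the shortest gene enclosing it, and any other region to the nearest protein-coding gene within 100 kb. Chromosome counts were tested with exact binomial tests (two-sided) against each chromosome's share of the length between its first and last annotated gene, adjusted by Benjamini-Hochberg over 21 chromosomes. Locations and neighbour counts were compared with 1000 random sets of equal size and equal chromosome counts. The 15 gene lists were fixed before the data were examined, as were the motifs and most of the other settings tried. For each list, the number of genes given a region was compared with 1000 random sets matched on chromosome class (autosome or sex chromosome), on lying inside a gene, and on distance to the nearest gene end in 7 bins. The empirical p-values are two-sided, cannot fall below 0.002, and were adjusted by Benjamini-Hochberg over the 15 lists. Current symbols were matched first and older ones through the table, and Cxcl11, Mx1, Il36rn and Il37 had no protein-coding match. The random stretches stand in for the accessible regions that were tested by the authors, a set not used here. They do not carry the uneven accessibility of real chromatin.

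The comparison of regions by width was chosen after the list was opened. It used Fisher's exact test, with a 95% interval from 1000 resamples of 5 Mb blocks, since neighbouring regions are not independent. Regions per gene were compared with the mean of the random sets by a one-sided Poisson test adjusted over all protein-coding genes. Exact intervals on shares (Clopper-Pearson, 95%) cover counting error only.

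Genes are named by a rule fixed beforehand: 11 genes in any case (among them Il1rn, Il1a, Il1b, Il1r1, Trp63, Krt5, Krt14, Krt8 and Fkbp5), up to 4 members per list with a region closest to a gene end, and the 10 genes with the most regions. Its part on the 5 widest regions selected nothing, since 3291 regions tie at the largest width, and its part on scores did not apply. Some genes that the rule selects are not reported here. Other genes named as members of a list were chosen after the positions were seen.

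The code was tested on simulated data. A plain search gave the same gene for 2000 of 2000 random positions. In 100 simulated sets in which 10 further genes of the NF-kB list received a region, that list was called in 50% of sets; with 5 further genes, it was called in 2%. With none added, the other lists were called in 0.0714% of their tests. For regions per gene, 7 extra regions were called in 99.2% of 200 changed genes and 3 extra regions in 43.2%, and on average over 20 sets 3.25 and 1.1 unchanged genes were called as well. With 0 extra regions a mean of 0 genes was called. The simulated sets were drawn from the same random positions as the background. Their rates of false calls therefore need not hold for the listed regions, which lie in groups. Alternatives covered the distance limit, the assignment, the background, the widths, autosomes alone, and merging of regions within 1 kb. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.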

Results

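Chromatin accessibility was profiled in basal prostate stem cells from 3 naive and 3 inflamed mouse prostates. The labelled genotype was WT for naive and POET3 for inflamed libraries, so inflammation and genotype cannot be separated. The list, read from its name and the named tools as one of regions differing between the groups, held 6502 regions. Together they covered 1944 kb of mm10. Regions came in 2 fixed widths. Of them, 3210 (49.4%) were 143 bases wide and 3291 (50.6%) were 451 bases wide, and a single region of 235 bases lay on chromosome 16 at 98107447 to 98107681. No source used here says what the widths stand for, and the list carries no direction, so no region is described as more or less open in inflamed cells. The depth of the libraries is unknown and no value has a replicate error.

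The listed regions lay close to genes. Of the 6502, 735 (11.3%, exact 95% interval 10.5 to 12.1) were centred within 1 kb of an end of a protein-coding gene, against 3.00% of random stretches. A further comparison placed 47.6% inside protein-coding genes, against 39.8% at random. Only 14.1% lay outside genes and over 100 kb from any of them, against 28.6% at random. Each difference had an empirical adjusted p of 0.002, the smallest the 1000 random sets can give. Accessible regions in general lie near genes, and the set of all accessible regions tested was not used here, so these values describe the list and not the part of open chromatin that changed.

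The widths differed in position. Regions of 451 bases were within 1 kb of a gene end in 16.96% of cases (exact 95% interval 15.7 to 18.3) and those of 143 bases in 5.51% (4.75 to 6.36). The difference was 11.4 percentage points (95% interval over resampled 5 Mb blocks 9.44 to 13.5, Fisher's exact test adjusted p = 3.9e-49 over 8 positions). The shares inside genes, 48.2% and 47.0%, differed by 1.18 percentage points, with an interval of -1.69 to 4.50 (adjusted p = 0.345). Around a 451-base region, a mean of 7.24 protein-coding genes started within 500 kb, below the 7.91 of random stretches. Around a 143-base region there were 11.4, above the random 8.52.

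**Figure D1:**
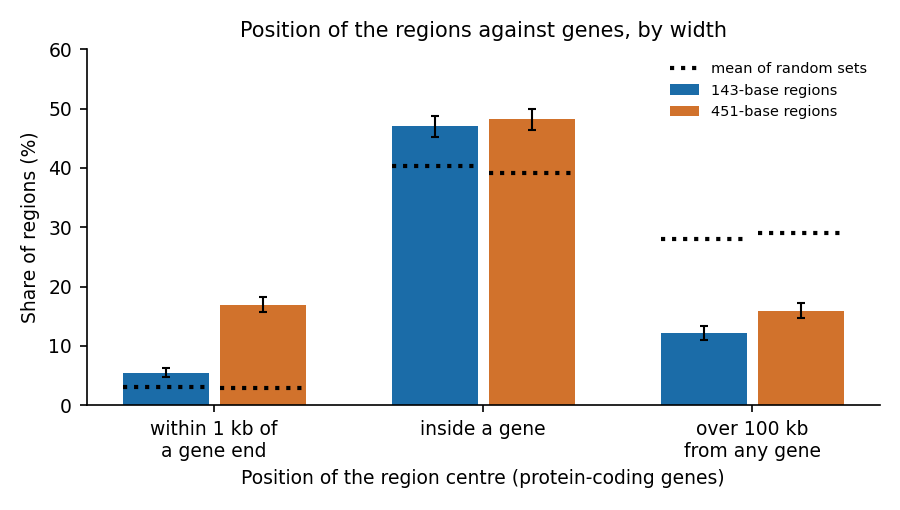
Share of regions (%, y axis) by the position of the region centre against protein-coding genes (x axis), for 143-base and 451-base regions. Error bars are exact 95% intervals and dotted lines are means of 1000 random sets; 16.96% of 451-base and 5.51% of 143-base regions lay within 1 kb of a gene end.

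Chromosomes 13 and 10 carried more regions than their length predicts and chromosome X fewer. Chromosome 13 held 401 regions, 1.42 times its share of annotated length (exact binomial test, adjusted p = 5.7e-11), and chromosome 10 held 417, or 1.36 times (adjusted p = 4.0e-09). Chromosome X held 207, or 0.504 times (adjusted p = 5.5e-29). Against its share of protein-coding genes in place of length, the deficit on X was smaller, at 0.721 times (exact binomial test, adjusted p = 9.1e-07). Chromosomes 3, 6, 18 and 19 were also above their share of length, at 1.19 to 1.27 times. Chromosomes 7 and 14 were below theirs, at 0.795 and 0.827 times. Adjusted p for chromosomes 3, 6, 7, 14, 18 and 19 ran from 1.7e-05 to 0.039 (exact binomial tests). With chromosome Y left out, chromosome 19 no longer passed (1.16 times, adjusted p = 0.13). Chromosome Y held 2 regions, 0.00915 times its share, and much of it is repeated sequence where reads are hard to place. The excess on chromosomes 13 and 10 was in the 451-base regions, with 8.14% and 7.84% of them against 4.14% and 4.95% of the 143-base regions. Chromosome 11, which is rich in genes, showed the opposite, with 6.88% of the 143-base and 2.55% of the 451-base regions (difference -4.33 percentage points, block interval -6.89 to -2.16). On chromosome X lay 5.04% of the 451-base and 1.28% of the 143-base regions (difference 3.77 percentage points, block interval 1.91 to 5.92). These tests treat regions as independent, which neighbouring regions are not.

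**Figure D2:**
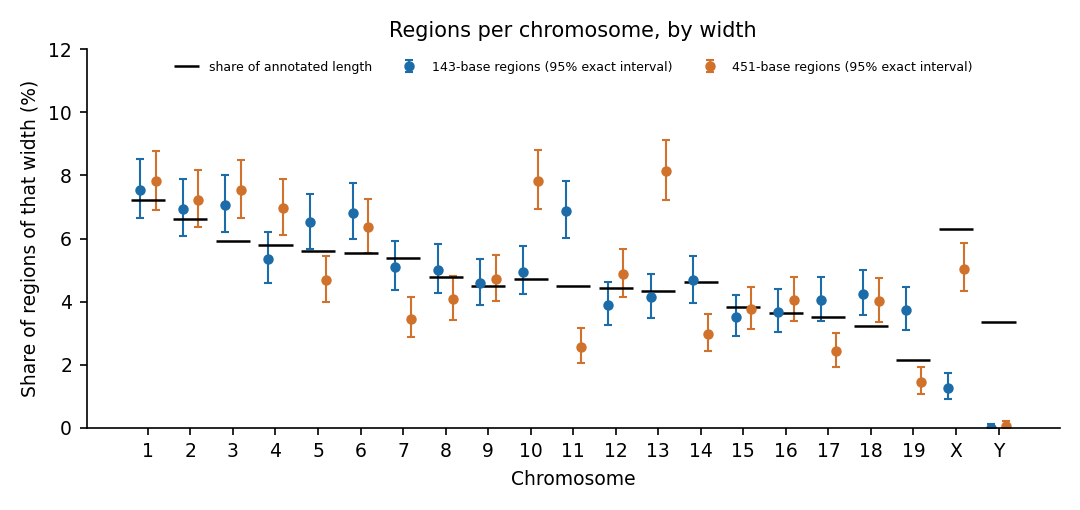
Share of the 143-base and of the 451-base regions (%, y axis) on each chromosome (x axis), with exact 95% intervals, beside the chromosome's share of annotated length (black lines). The 451-base regions stand above that share on chromosomes 10 and 13, and the 143-base regions on chromosomes 11 and 19.

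NF-kB genes and genes of the IL-1 family and its signalling were given listed regions more often than matched random sets gave them. Of the 28 genes in the list of NF-kB pathway members and targets, 14 had at least 1 region, against a random mean of 4.76 (95% range 1 to 9), a 2.94-fold excess (empirical test, adjusted p = 0.030 over 15 lists). The list of the IL-1 family and its receptors has 23 genes and also holds signalling genes, among them Irak2, Irak4 and Tollip. Of the 23 genes, 10 had a region, including these signalling genes, against 4.17 (range 1 to 8), a 2.40-fold excess (adjusted p = 0.045). The IL-1 call sat at the threshold. With 10000 random sets in place of 1000 its adjusted p was 0.052 and that of the NF-kB list 0.0030, and with genes within 500 kb of each other counted once it was 0.19, against 0.030 for the NF-kB list. Near gene ends alone (within 1 kb), 4 NF-kB genes and 2 IL-1 genes had a region, and neither list passed (adjusted p = 0.21 and 0.78). The largest fold at that setting was that of the interferon list. It had 4 of 25 genes against 0.77 (5.19-fold, empirical test, adjusted p = 0.21), beside 5.10-fold for the NF-kB list. Neither passed with either width alone. Both lists together had a region at 24 of 51 genes (47.1%), and the basal and luminal epithelial markers together at 16 of 44 (36.4%). That difference did not pass (Fisher's exact test, two-sided, p = 0.31). The Fisher test compares shares and leaves out the random means. Over those, the basal list stood at 1.61-fold and the luminal list at 1.72-fold, and neither passed.

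**Figure D3:**
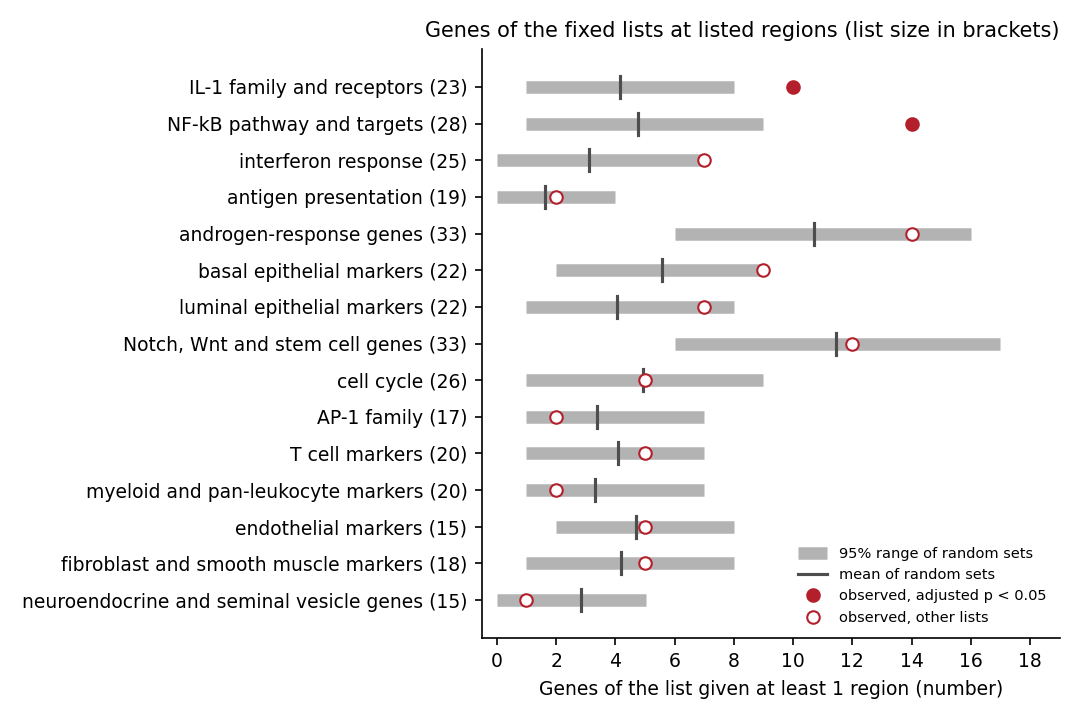
Number of genes given at least 1 region (x axis, circles) for each of the 15 fixed lists (y axis, list size in brackets), against the mean (dark ticks) and 95% range (grey bars) of 1000 matched random sets. The IL-1 list (10 genes) and the NF-kB list (14 genes) lie right of their ranges.

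Among NF-kB genes, Tnfaip3, which encodes the inhibitor A20, had 4 regions of 451 bases. The nearest was centred 24 bases outside the gene, at 19015210 to 19015660 on chromosome 10. Another lay inside the gene, and the others were 38.6 and 47.0 kb outside it. Relb, a subunit of NF-kB, had a 143-base region inside the gene 0.732 kb from its end (chromosome 7, 19628636 to 19628778). The chemokine genes Cxcl5 and Ccl20 had regions 0.919 and 0.960 kb outside the gene, of 451 bases for Cxcl5 and of 143 bases for Ccl20. Lif, which encodes a cytokine of the IL-6 family, had 4 regions of 143 bases, and Nfkbiz, an NF-kB cofactor, had 3. The inhibitor genes Nfkbia and Tnip1 and the chemokine genes Cxcl2 and Ccl2 were also among the 14.

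In the IL-1 list, Il1rn, which encodes the IL-1 receptor antagonist, had 2 regions of 143 bases. The gene (NCBI gene 16181) spans 24336860 to 24351491 on chromosome 2. The first region lay just outside it, centred 0.093 kb from its end (24336696 to 24336838), and the other inside it (24341546 to 24341688). The receptor cluster on chromosome 1 held regions inside Il1r2, Il1rl1, Il18r1 and Il18rap, and none was given to Il1r1, whose nearest region was 101 kb away, inside Il1rl1. Irak4, a kinase of IL-1 receptor signalling, had a 451-base region across its gene end on chromosome 15 (94543388 to 94543838). Il1b had a single 451-base region 40.8 kb away. None was given to Il1a, although a 451-base region lay 2.38 kb from it and was given to the nearer gene Ckap2l.

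**Figure D4:**
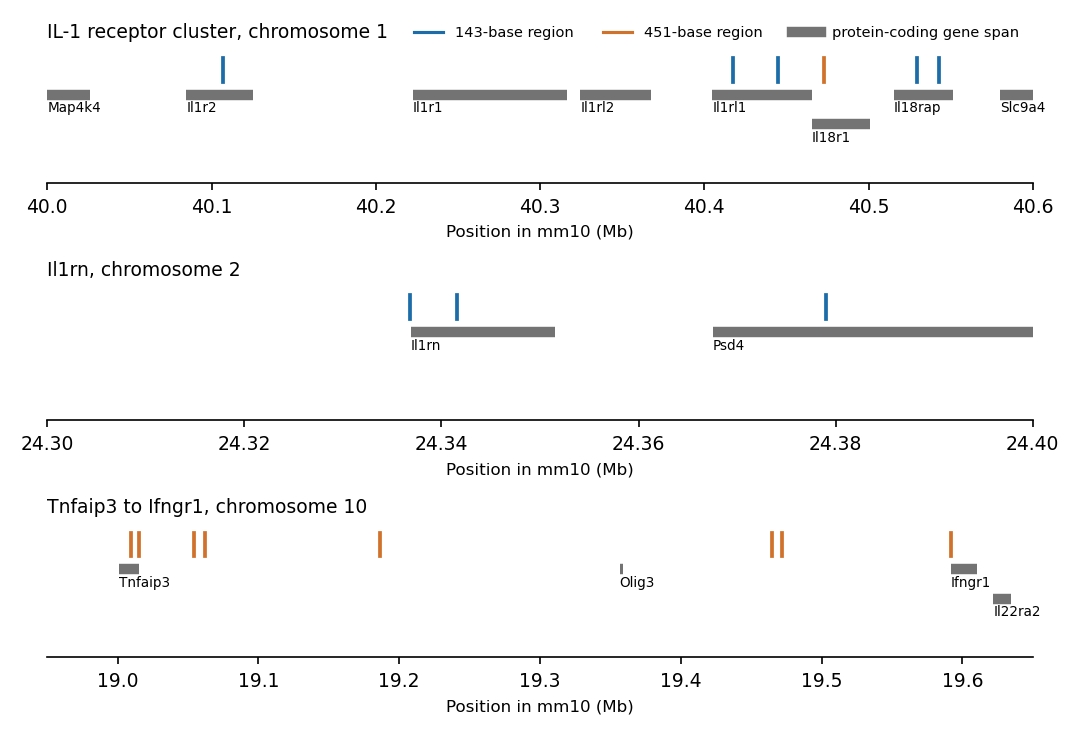
Listed regions (vertical marks, coloured by width) and protein-coding gene spans (grey bars) along mm10 in Mb (x axis) at the IL-1 receptor cluster, at Il1rn, and from Tnfaip3 to Ifngr1. The marks at Il1rn are of 143 bases and the 4 given to Tnfaip3 are of 451 bases. Mark thickness is not to scale.

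The list of androgen-response genes did not stand out. Of its 33 genes, 14 had a region, against a random mean of 10.7 (95% range 6 to 16, 1.31-fold, adjusted p = 0.57). Steap4, a metalloreductase gene, had a total of 3 regions, among them a 451-base region across its gene end, centred 0.030 kb outside the gene. The others were 42.5 and 67.9 kb outside it. Mme, which encodes neprilysin, had a 451-base region 0.628 kb inside its end, and Nedd4l, a ubiquitin ligase gene, a 143-base region 2.97 kb outside. None was given to Fkbp5, a classical androgen target, whose nearest region was 142 kb away.

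Of the 22 basal markers, 9 had a region, against 5.59 at random (adjusted p = 0.51). The widths lay on opposite sides of random, and neither passed. With 143-base regions alone, 8 genes had one against 3.37 (2.37-fold, empirical test, adjusted p = 0.12). With 451-base regions alone, 1 had one against 3.01 (0.332-fold, empirical test, adjusted p = 0.80). Trp63, the basal lineage transcription factor p63, had 3 regions of 451 bases, the nearest to a gene end being 7.12 kb outside it. The other 8 of these members of the basal list, among them Krt14, Krt17, Tspan1, Col17a1 and Egfr, had 143-base regions only. The region of Krt14 lay 14.4 kb away and that of Krt17 1.34 kb away. Krt5 was given none, with the nearest region 12.6 kb away and closer to Krt6a. Of the 22 luminal markers, 7 had a region, against 4.07 (adjusted p = 0.57). They included the claudin gene Cldn3, with a 143-base region across its gene end, centred 0.052 kb outside, Krt19, with one centred 0.133 kb outside, and Cldn4. None was given to Krt8, whose nearest region was 275 kb away. In the test of widths by list, which drew random sets of genes that had regions, no list passed, and the lowest adjusted p was 0.57. Basal genes had 3 regions of 451 bases and 11 of 143 bases (permutation p = 0.094 before adjustment), and fibroblast and smooth muscle genes had 8 and 1 (permutation p = 0.043).

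The interferon list had 7 of 25 genes with a region, against 3.12 at random (2.24-fold, adjusted p = 0.29). Ifngr1, a subunit of the interferon-gamma receptor, had a 451-base region across its gene end, centred 0.085 kb outside the gene. Ido1, Ifit2 and Gbp3 had a region centred within 0.22 kb of a gene end. The antigen presentation list had 2 of 19, Cd74 with a 143-base region 0.132 kb outside the gene and Ciita, the class II transactivator. The list of Notch, Wnt and stem cell genes had 12 of 33, with a fold over random of 1.05. Myc had a 451-base region across its gene end, centred 0.061 kb outside the gene, and Jag1, Lgr5 and Lgr4 were also given a region. The cell cycle list had 5 of 26, against 4.92, among them the inhibitor gene Cdkn2b, with a 451-base region across its gene end, Cdk6 with 6 regions, Cdk1 and Ccne1. The AP-1 list had 2 of 17, Batf3 and Jun, against 3.38. None of these lists passed, nor did any list below.

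Markers of other cell types did not pass the test. The gate should leave out the leukocytes and endothelial cells among them. T cell markers had 5 of 20 genes, against 4.08, namely Cd247, Cd5, Cd6, Ifng and Cd28. Myeloid and pan-leukocyte markers had 2 of 20, Mrc1 and Ptprc, against 3.33. Endothelial markers had 5 of 15, against 4.68, among them Tek, Flt1, Erg and Vwf. Fibroblast and smooth muscle markers had 5 of 18, against 4.20, among them Vim, Acta2, Col3a1 and Dcn. The adjusted p of each of these 4 lists was 1.

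In all, 5587 regions (85.9%) were given to 3708 protein-coding genes, of which 2558 had a single region. The most were at Macrod2, with 15, a gene of 1998 kb for which random sets gave a mean of 4.54 (adjusted p = 0.18). Next, with 8 each, were Astn2, Fat1, Fhit, Nhsl1, Pde4d and Snx13, followed by Anks1b, Arhgef28 and Itga1 with 7. Astn2, Fhit, Pde4d and Anks1b span over 1000 kb. Of the 10, only Fat1, Snx13 and Nhsl1 exceeded random placement after adjustment. Fat1, which encodes a giant cadherin, had 12.1 times its random mean (Poisson test, adjusted p = 0.0068), Snx13, a sorting nexin gene, 11.8 times (adjusted p = 0.0068) and Nhsl1 10.4 times (adjusted p = 0.011). All 8 regions at Nhsl1 were 451 bases wide, while Fat1 had 4 of each width. The Poisson test leaves out the clustering of accessible regions, which makes its p-values too small.

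Regions lay in groups. A neighbour within 10 kb was found for 801 regions (12.3%), against a mean of 329 in random sets (95% range 281 to 375, a 2.44-fold excess). Counted within a width, the excess was 5.41-fold for 143-base and 2.71-fold for 451-base regions. The empirical p of each was 0.002, the smallest the random sets can give. The random sets do not carry the uneven accessibility of real chromatin. The excess therefore describes the list and not the part of open chromatin that changed. Of the 414 adjacent pairs that close, 355 (85.7%) had equal width, 231 of them of 143 bases and 124 of 451 bases, against 50.0% when widths were shuffled (permutation p = 0.0002, the smallest possible). Of the 3708 genes, 460 had regions of both widths, 1703 of 143 bases only and 1544 of 451 bases only.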

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

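Chosen only after the data were seen were the tests on 143-base regions alone, the nearest gene end, genes counted once, random gene lists, 10000 sets, shares of protein-coding genes, leaving out chromosome Y and resampled blocks, and the comparison of widths itself. No paired analysis was possible because the list holds no values per library, so neither the replicate numbers shared by the groups nor leaving out a library could be used. The location shares, the deficit on chromosome X, the neighbour count and the difference between widths near gene ends kept their direction and stayed past the threshold in each alternative run for them. Their size moved: the excess near gene ends ranged from 1.78-fold (143 bases) to 5.88-fold (451 bases), the share on X from 0.202 to 0.799 times its length, and the neighbour excess from 1.86-fold (50 kb) to 5.41-fold (143 bases). Using the 451-base regions alone (those at least as wide as the median) or the 143-base regions alone left 3291 and 3210 regions. The number of lists called fell from 2 to 0 with 451-base regions alone, with 143-base regions alone and within 1 kb of a gene end. It fell to 1, the NF-kB list, when regions within 1 kb were merged, when list genes within 500 kb counted once, and with 10000 random sets. The IL-1 excess of 2.40-fold was then 1.85-fold (451 bases), 2.52-fold (143 bases), 3.09-fold (gene ends), 2.42-fold (merged), 2.05-fold (genes counted once) and 2.40-fold (10000 sets), with adjusted p from 0.052 to 0.80. The NF-kB excess of 2.94-fold was 2.27-fold (451 bases), 3.55-fold (143 bases) and 5.10-fold (gene ends), with adjusted p from 0.060 to 0.72. Fewer regions or genes entered under each width and near gene ends, and for merging and 10000 sets the IL-1 values differ by little from the main one. The other 13 lists stayed short of the threshold in 13 alternatives each. In the simulated sets a list with 5 added genes was rarely called, so lists short of the threshold are not shown to be at random level. Motif results, GC matching and results by direction were not run, for want of sequence and of a direction.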

Other observations

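The tests chosen only after the result was seen were those of gene families, leukocyte markers, epithelial markers, shuffled widths, GC content and the single X copy. Besides the fixed lists, 30 gene families defined by symbol were examined, some of which share genes with those lists. Sensory receptor genes were nearly empty of regions. Of 1110 olfactory receptor genes, 4 were given a region, 0.0406 times the mean of matched random sets, and of 353 vomeronasal receptor genes 1, or 0.0164 times the random mean (both adjusted p = 0.020 over 30 families). Of 397 zinc-finger Zfp genes, 36 had a region, against 69.8 (adjusted p = 0.020). These families sit in arrays, so their members are not independent. The random sets do not carry the uneven accessibility of real chromatin. These deficits therefore describe the list and not the part of open chromatin that changed. No family passed above random. The families nearest to it were the claudins, with 8 of 23 genes against 3.57, the desmosomal cadherin and plaque genes, with 8 of 15 against 3.72, and the TNF ligands and receptors, with 11 of 31 against 5.86 (each adjusted p = 0.11). The desmosomal genes were Pkp1, Pkp2, Pkp4, Dsc1, Dsc2, Dsc3, Dsg1c and Dsg2. The TNF family genes included Tnfsf11 (RANKL), its receptor Tnfrsf11a and its decoy receptor Tnfrsf11b. Some of these genes are not independent either. At least Dsc1, Dsc2, Dsc3 and Dsg1c lie close together on chromosome 18, and Cldn3 and Cldn4 on chromosome 5. Dsc3 is also in the basal list, and Cldn3 and Cldn4 are in the luminal list.

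The excess at IL-1 and NF-kB genes may reflect leukocytes that passed the gate against CD45-positive cells, which stays open: 7 of 40 T cell and myeloid markers had a region, against a random mean of 7.41, and the comparison with the 24 of 51 genes of both lists (Fisher's exact test, p = 0.0038) excludes nothing, since these lists were picked for their excess. Uneven accessibility stays open too. Against 10000 random gene lists with the same chance of a region the larger adjusted p of both lists was 0.018, but such lists also draw genes closed in these cells. The basal and luminal markers had a region in 16 of 44 genes (Fisher's exact test against the 24 of 51, p = 0.31). That comparison of shares leaves out the random means, over which these lists stood at 1.61-fold (basal) and 1.72-fold (luminal). Neighbouring genes of a cluster stay open for the IL-1 list: counted once within 500 kb, 7 of 13 loci had a region against 3.42 at random (2.05-fold, adjusted p = 0.19), so the call ended with fewer units and a fold not far below the 2.40 of single genes, while the NF-kB list had an adjusted p of 0.030. The labelled genotype coincides with the group, so inflammation and genotype cannot be separated for any region.

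The 451-base and 143-base regions lay apart, which random widths within a single list would not give: 85.7% of adjacent pairs within 10 kb had equal width. Regional make-up at the scale of 5 Mb is not enough either, since widths shuffled within 5 Mb blocks gave at most 67.6% (upper bound of the 95% range). Make-up that varies over shorter stretches stays open, because the shuffle does not keep it. Within a width, centres were never closer than 282 bases (143-base regions) or 1164 bases (451-base regions), and between widths never closer than 1404 bases. A hypothesis is that each width comes from its own region calling, for example of either group or of either direction, merged afterwards, but separate calling could also have placed some regions of unlike width closer than that, and no value here assigns a width to a group. GC content stays open: from the least to the most gene-dense 5 Mb blocks the ratio of 451-base to 143-base regions changed by a factor of 0.353, as GC bias between libraries could produce, and no sequence was used here.

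Chromosome X held 1.28% of the 143-base and 5.04% of the 451-base regions. Male cells have a single X, which lowers reads there, and this stays open: the interval of the difference began at 1.91 percentage points, but whether a lower depth acts on both widths alike was not tested. Lower gene density around 451-base regions is not enough as an explanation, since the widths differed on X both where genes were sparse and where they were dense (larger Fisher p = 8.1e-06). Regions were taken as independent in that last test, and 166 of the 207 regions on X were of 451 bases. What the widths stand for, the group and the labelled genotype may each still account for it, and none of these was tested.

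On chromosome 10, the block from 15 to 20 Mb, which holds Tnfaip3, Ifngr1 and Nhsl1, had 37 regions of 451 bases and 6 of 143, and that from 95 to 100 Mb had 36 and 5. The mean per autosomal 5 Mb block was 6.54 for 451-base and 6.56 for 143-base regions, with SDs over 464 blocks of 6.64 and 3.91.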
